A study of Streptococcus thermophilus ASCC 1275 and Levilactobacillus brevis
Streptococcus thermophilus ASCC 1275 with 6 samples.

How the data were processed

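RNA was measured in 6 libraries of fermented milk taken after 18 h: 3 replicates of milk fermented by Streptococcus thermophilus alone (S, the monoculture) and 3 replicates of milk fermented by Streptococcus thermophilus together with Levilactobacillus brevis NPS-QW 145 (SL, the co-culture). Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was depleted with a Ribo-Zero kit, and the fragmented RNA was made into strand-marked cDNA libraries with dUTP. The submitters' processing notes name cutadapt 1.9 and Bowtie2 2.2.0. The assembler, the counting step, the reference sequences and any filter on unigenes are not given in the sources used here. A unigene is a transcript sequence that stands for one gene of the mixed community.

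The deposited table holds 1 abundance per library for each of 3058 unigenes, with no pooling of replicates, and all 6 columns were matched to samples by their names. Neither its header nor the labels name the unit. The deposited values were treated as TPM (transcript abundance corrected for length and scaled to a total of 1000000 per library), because each column summed to 1000000 within 0.0012 and because low values in a column shared no common step, as they would if 1 read were worth the same for every unigene. TPM keeps no depth, so the number of reads per library is unknown and no counting interval was computed. Ratios of low values to those of S replicate 1 gathered at a value per library (within 0.04 on the log2 scale) and also at 2 to 1 of it, so the relative depth of the libraries stays open by a factor of 2 or more.

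The table identifies unigenes by number only, without gene names, sequences or taxa. The lists of metabolic, stress, transport and other gene groups fixed before the data were examined therefore could not be matched, no gene list was tested, and unigenes were not assigned to either bacterium. The table holds no value of 0 for S replicate 1, against 63 to 75 such values in each of the other 5 libraries, so a unigene without reads in S replicate 1 could not be seen.

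The following results were computed. The first was limma (version 3.58.1, R 4.3.3; eBayes with trend and robust) on log2(TPM + 1) over unigenes with at least 1 TPM in at least 3 of the 6 libraries, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on the log2(TPM + 1) scale, which understates the change of low unigenes. The second repeated the fit on unigenes above 0 in at least 2 of the 3 S libraries, after rescaling each library to the same total (1000000) over them. This was meant to remove the dilution of Streptococcus thermophilus transcripts by those of the second bacterium, but it kept 3044 of the 3058 unigenes and so rescaled almost nothing. A fit on unigenes with a mean of at least 10 TPM in S, rescaled over these, was added after seeing the data. These held 97.4% of the SL abundance, so this rescaling also removed little (0.034 on the log2 scale). The fit is on unigenes with a high mean in S and not a correction for dilution. That mean can rest on 1 library, as for Unigene999, at 1.07, 0.931 and 533 TPM in S replicates 1, 2 and 3. The third was the share of summed abundance from unigenes at 0 in all S libraries, with an exact two-sided permutation test, which cannot go below p = 0.1 with 3 against 3.

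The unigenes named are, by a rule fixed before the data were examined, the 2 with the largest rise and the 2 with the largest fall past the threshold whose groups do not overlap in the second fit. The rule also asked for the 2 most abundant unigenes at 0 in all S libraries, and there were none. Unigenes mentioned only by abundance rank were chosen after their values were seen.

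Alternatives were median of ratios scaling, limma without trend and robust, no low-value filter, a minimum of 10 TPM, pseudocounts of 0.1 and 10, the replicate number as a block, each library left out in turn, and other definitions of detection in S. The limma code was tested on simulated data with the SDs of the real libraries, shuffled over unigenes. Changed unigenes were drawn only from those with a mean log2(TPM + 1) above log2(10). Over 5 draws they were 500 per fold size, against 9055 left unchanged. For SL against S over 2011 unigenes, it called 26.8% of unigenes changed 2-fold, 73.6% of those changed 4-fold and 0.177% of those left unchanged. These rates hold for that setting. They do not carry over to low unigenes or to the real fit, where a far larger part of the unigenes was called. Descriptive values were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.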

Results

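Streptococcus thermophilus is a lactic acid bacterium used as a starter for fermented milk. Levilactobacillus brevis is a lactic acid bacterium of which many strains convert glutamate to gamma-aminobutyric acid (GABA), and the series title concerns its GABA production in co-culture. The design compared RNA from milk fermented for 18 h by Streptococcus thermophilus ASCC 1275 alone (monoculture, 3 libraries) with RNA from milk fermented for 18 h by the same bacterium together with Levilactobacillus brevis NPS-QW 145 (co-culture, 3 libraries). Abundances of 3058 unigenes were given as values that sum to 1000000 in each library and were read as TPM. Read totals are unknown, so precision rests on the spread between the 3 libraries of a group. The labels do not say whether replicates were separate fermentations, and p-values then measure only the spread between these libraries. Unigenes are numbered and not named, so transcripts of glutamate decarboxylase, the enzyme that makes GABA, were not analysed here.

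Far more unigenes were well represented in the co-culture than in the monoculture. At least 1 TPM was reached by 1448 ± 42.8 unigenes in the monoculture and 2065 ± 75.7 in the co-culture (SD, n = 3 each), and the median unigene stood at 0.879 ± 0.0497 TPM against 4.01 ± 1.26 TPM. The lowest co-culture library lay above the highest monoculture library for both measures. The exact two-sided permutation p was 0.1 for each, the smallest that 3 against 3 allows. Replicates resembled each other more than they resembled the other group: across the 2011 unigenes tested, the correlation of log2(TPM + 1) was 0.965 to 0.992 within the monoculture, 0.929 to 0.966 within the co-culture and 0.758 to 0.876 between them.

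The first comparison asked which transcripts changed when the second bacterium was present. Of 2011 unigenes tested, 1105 rose and 366 fell in the co-culture, and 540 did not pass the test (limma, Benjamini-Hochberg adjusted p under 0.05). Changes were large: 691 of the risers rose at least 4-fold and 53 of the fallers fell at least 4-fold. The groups did not overlap for 1601 unigenes (79.6%). For 3 against 3, chance gives 10% where no filter is applied. A unigene that passed the low-value filter only through the 3 co-culture libraries could not overlap, so 10% is not the chance share here. The direction depended on abundance. Among 592 unigenes with a mean of 10 to 100 TPM over all 6 libraries, 338 rose and 112 fell, whereas among 127 with a mean of 1000 TPM or more, 28 rose and 71 fell. Median of ratios scaling, which lowered co-culture values by 1.05 on the log2 scale relative to the monoculture, gave 842 risers and 636 fallers, so the split of 75.1% risers became 57.0%. Leaving out a co-culture library reduced the tested unigenes to between 1562 and 1578 and the calls to 934 without replicate 1, 977 without replicate 2 and 971 without replicate 3, counts that were the same in the second comparison.

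The unigenes fell into 2 populations. The log2 ratio of mean TPM, co-culture over monoculture, had one peak between -0.5 and 0 with 345 unigenes and another between 3.5 and 4 with 317, and a valley between 1 and 1.5 with 116. In total 1215 unigenes (39.7% of the table) had a mean at least 4 times higher in the co-culture, with a median ratio of 12.5. Of these, 1031 could be tested and 1001 passed. Only 109 unigenes were at least 4 times lower in the co-culture, of which 71 of 77 tested passed.

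**Figure D1:**
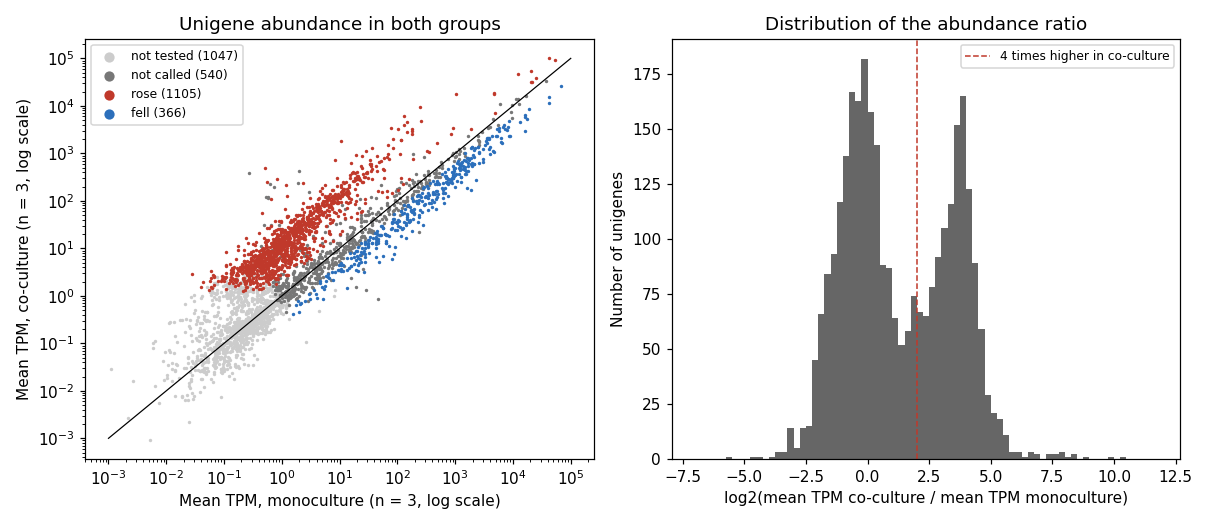
Left, mean TPM of each unigene in the monoculture (x, log scale, n = 3) against the co-culture (y, log scale, n = 3), coloured by the limma call, with the line of equality; right, number of unigenes by log2 ratio of the means, with a dashed line at 4 times higher. Unigenes at 0 in all 3 libraries of the co-culture (6) have no ratio and are left out; the 1105 risers lie above the line, and the ratios have 2 peaks.

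The share of RNA from transcripts specific to the co-culture was addressed with unigenes at 0 in all 3 monoculture libraries. No unigene met this definition, since S replicate 1 holds no 0, and the share was 0 in both groups. A looser definition, with a monoculture mean under 1% of the co-culture mean, gave 17 unigenes, which took 0.00245% ± 0.000468 of the monoculture and 0.533% ± 0.152 of the co-culture (SD, n = 3 each). The 1215 unigenes at least 4 times higher in the co-culture took 0.757% ± 0.308 of the monoculture and 13.5% ± 4.83 of the co-culture, with 18.6%, 9.06% and 12.7% in co-culture replicates 1, 2 and 3. Both classes were set on the values they are read in. Set on replicate 1 alone, the class of at least 4 times higher held 1274 unigenes, which in replicates 2 and 3 took 2.96% ± 1.19 of the monoculture and 18.0% ± 2.67 of the co-culture (SD, n = 2 each).

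**Figure D2:**
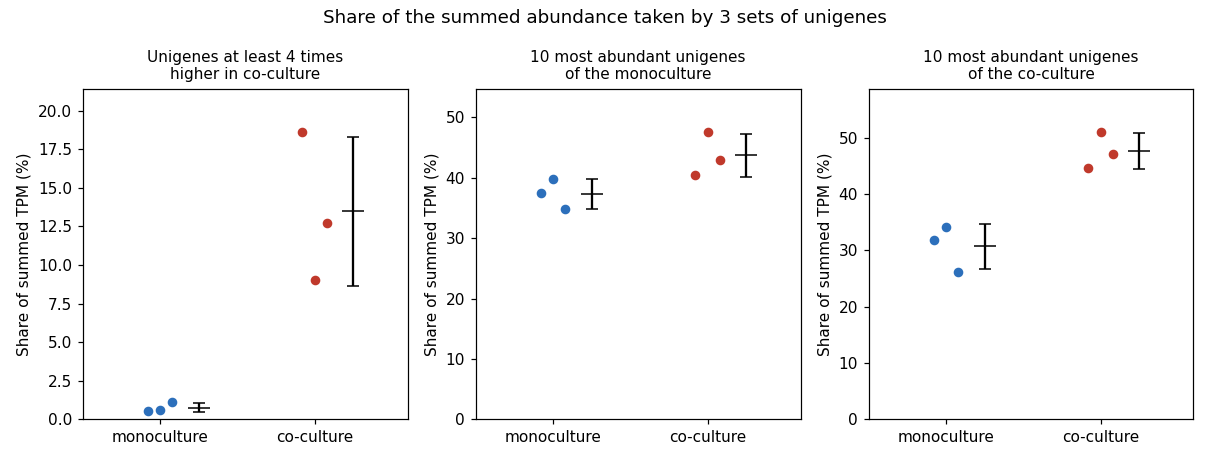
Share of the summed TPM (y, %) taken by the unigenes at least 4 times higher in the co-culture (left), the 10 most abundant of the monoculture (middle) and the 10 most abundant of the co-culture (right). Points are libraries, and the bar beside them is the mean with its SD (n = 3); the left set goes from 0.757% to 13.5% and the right set from 30.7% to 47.6%.

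A few transcripts held a large share of the RNA, larger in the co-culture. The 10 most abundant unigenes of each library took 37.7% ± 1.96 of the monoculture and 48.0% ± 2.77 of the co-culture (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). Between 16 and 19 unigenes made up the first 50% of abundance in a monoculture library, and between 10 and 13 in a co-culture library. Both groups shared 8 of their 10 most abundant unigenes, in another order. The first of the monoculture went from 6.85% ± 1.18 to 2.63% ± 0.162 of the abundance (log2 fold change -1.36, SE 0.16, limma adjusted p = 0.000424), and the first of the co-culture from 4.26% ± 1.10 to 10.2% ± 1.13 (log2 fold change 1.29, SE 0.21, limma adjusted p = 0.00114). Of the 10 leading unigenes of the monoculture, 6 rose, 3 fell and 1 did not pass. The rises depended on the scale: with median of ratios over all unigenes none of the 10 rose and 4 fell, and with median of ratios over unigenes of at least 10 TPM in the monoculture 6 rose and 2 fell.

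The second comparison asked how transcripts present in the monoculture changed. The planned set, unigenes above 0 in at least 2 of 3 monoculture libraries, held 3044 of 3058 unigenes, and its result was nearly that of the first comparison: 1104 rose, 366 fell, and all 1470 calls were among the 1471 of the first. A set with a monoculture mean of at least 10 TPM, added after seeing the data, held 721 unigenes that made up 99.7% ± 0.0375 of the monoculture and 97.4% ± 0.893 of the co-culture abundance. Rescaling over these shifted the groups by 0.034 on the log2 scale, so dilution by the second bacterium was not removed, and choosing on the monoculture level favours falls. In this set 340 fell and 142 rose in the co-culture, with 239 not passing (limma, adjusted p under 0.05). The falls were mostly moderate, with 255 of at least 2-fold and 50 of at least 4-fold, whereas 112 of the 142 rises were at least 4-fold. Unigene999, among these rises, reached the mean of 10 TPM through monoculture replicate 3 alone. Others also had an SD above their mean in the monoculture, such as Unigene1154 (65.7 ± 111 TPM after rescaling), Unigene249 (52.2 ± 88.6) and Unigene1157 (48.0 ± 81.1). The 142 and the 112 rises thus include transcripts that were not at 10 TPM in every monoculture library. How many was not counted. The median log2 fold change was -0.58. With median of ratios scaling, which raised co-culture values by 0.61 on the log2 scale, 174 fell and 193 rose. That scaling, set on these same unigenes, places their median change near 0 (0.0139) by construction. A near-equal split was thus built in and does not test the excess of falls, which rests on the scale chosen.

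By the naming rule, on the log2(TPM + 1) scale, the largest rise in the second comparison was in Unigene989. It went from 10.7 ± 0.407 TPM to 1841 ± 1038 TPM (SD, n = 3 each), with a log2 fold change of 7.16 (SE 0.38, limma adjusted p = 0.000131). All 3 monoculture libraries were between 10.3 and 11.1 TPM. Unigene999 came next with a log2 fold change of 6.93, SE 2.27 and limma adjusted p = 0.0298, but its monoculture libraries disagreed, at 1.07, 0.931 and 533 TPM in replicates 1, 2 and 3. In the co-culture Unigene999 stood at 1006, 657 and 5847 TPM. Its call was lost with median of ratios scaling over all unigenes (log2 fold change 6.03, adjusted p = 0.11) and when any library but S replicate 3 was left out (log2 fold change 5.56 to 7.56, adjusted p from 0.0678 to 0.107), and kept with median of ratios scaling over unigenes of at least 10 TPM in the monoculture (log2 fold change 7.46, adjusted p = 0.0392). Over all alternatives its limma adjusted p ranged from 0.001 to 0.11. By the same rule and scale, the largest falls were in Unigene1478 and Unigene2941. Unigene1478 went from 82.0 ± 37.8 TPM to 5.97 ± 0.775 TPM (log2 fold change -3.48, SE 0.39, limma adjusted p = 0.00042). Unigene2941 went from 1881 ± 766 TPM to 170.1 ± 42.6 TPM (log2 fold change -3.42, SE 0.33, limma adjusted p = 0.00032). Unigene989, Unigene1478 and Unigene2941 kept their direction and their call in every alternative that tested them. The order of the named unigenes depended on the scale and on single libraries. Unigene999 rose more than Unigene989 in some alternatives, such as a pseudocount of 0.1 (log2 fold change 7.51 against 7.28). Unigene2941 fell more than Unigene1478 with median of ratios scaling (-4.46 against -4.44) and a pseudocount of 10 (-3.35 against -2.45). It also did so without S replicate 1 (-3.59 against -3.14), without S replicate 2 (-3.56 against -3.53) and without SL replicate 2 (-3.53 against -3.39). By the ratio of mean TPM, other unigenes rose more, up to a log2 ratio between 10 and 10.5. The lowest log2 ratio lay between -6 and -5.5, a range that held 1 unigene, Unigene762. Its monoculture libraries varied widely (46.1 ± 78.1 TPM after rescaling over the set of at least 10 TPM, against 0.884 ± 0.533 TPM in the co-culture). Its groups overlapped and it did not pass in that set (limma adjusted p = 0.295). No genomic position or gene name was used here for these unigenes.

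**Figure D3:**
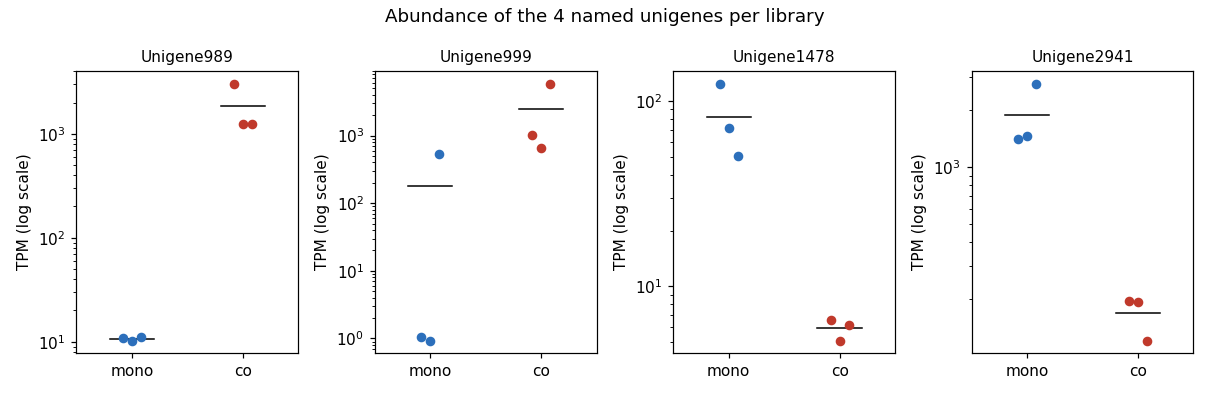
TPM per library (y, log scale, a separate range in each panel) of the 4 named unigenes in the monoculture (mono, n = 3) and the co-culture (co, n = 3), with the mean as a line. Groups are apart in each panel, and 1 monoculture library of Unigene999, replicate 3 at 533 TPM, lies near the co-culture.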

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

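Counts of changed unigenes stayed within 1.5 times the main 1471 (all unigenes) and 1470 (detected in S) with median of ratios scaling, limma without trend and robust, no low-value filter, pseudocounts of 0.1 and 10, a 2-fold minimum and detection in all 3 S libraries. A minimum of 10 TPM gave 783 in both fits, with 1009 unigenes tested. A mean of at least 1 TPM in S gave 958, at least 10 TPM gave 482 and at least 100 TPM gave 261. A mean of at least 10 TPM gave 367 with median of ratios scaling and 547 with S replicate 3 left out of the fit. In the latter the mean still included S replicate 3, so unigenes chosen through that library alone stayed in the set. Each of these settings tests fewer unigenes. Leaving out 1 library gave 934 to 1452 calls over all unigenes and 934 to 1450 among those detected in S. Without a co-culture library 934 to 977 unigenes passed of 1562 to 1578 tested. Without a monoculture library 1288 to 1452 passed (1285 to 1450 among those detected in S) of 1976 to 1991 tested. These fits still asked for at least 1 TPM in at least 3 libraries. A unigene reaching 1 TPM only in the 3 co-culture libraries thus left the test when 1 of them was dropped. Whether that is the whole reason for the lower share was not tested. Over all unigenes, risers made up 75.1% of calls in the main fit and 57.7% with a minimum of 10 TPM. They made up 65.3% to 69.8% without a co-culture library and 72.4% to 77.3% without a monoculture library. With the replicate number as a replicate block, 1465 and 1464 unigenes passed, and no named unigene lost its call. Same-numbered libraries did not deviate together in every pair (correlations of 0.0113, 0.204 and 0.265), and S replicate 1 correlated best with SL replicate 2 (0.263), so the numbers were not taken to pair the samples. The share of co-culture abundance from unigenes not detected in S was 0 in the main definition, and leaving out 1 library gave 0 to 0.000505%. S replicate 1 holds no value of 0, so the share was fixed at 0 wherever that library was kept. The range is thus no measure of stability. Looser classes hold unigenes that are above 0 in S and do not measure that share. They took 0.533% of the co-culture with a monoculture mean under 1% of the co-culture mean and 13.5% for unigenes at least 4 times higher. The class set on replicate 1 took 18.0%. Definitions by a mean of at least 10 or 100 TPM, the class of at least 4 times higher and the settings joined to them were chosen after seeing the data. Gene list tests were not run, for want of gene names. Depth limits low unigenes to an unknown degree, since TPM holds no read totals.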

Other observations

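All tests in this part were chosen after the results they bear on were seen. Libraries also differed within a group. In co-culture replicate 3, 23 unigenes reached 20 TPM and stood at least 10 times above both other co-culture libraries, together 1.37% of that library. The same was seen for 8 unigenes in co-culture replicate 1 and 2 in replicate 2, and for 23 in monoculture replicate 3 against 3 and 2 in monoculture replicates 1 and 2. Unigenes with consecutive numbers had more similar changes than chance: the correlation of log2 ratios between neighbours, across unigenes, was 0.142, against at most 0.0739 in 100000 shuffles (permutation p = 1e-05, the smallest they can give).

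The first pattern is a set of transcripts high in monoculture replicate 3 and in the co-culture. Chosen on the monoculture, 32 unigenes stood in replicate 3 more than 10 times above replicates 1 and 2, and 22 of them, Unigene999 among these, were at least 5 times higher still in co-culture replicate 3; the 22 took 0.00254%, 0.00205% and 0.184% of monoculture replicates 1, 2 and 3, and 0.361%, 0.229% and 1.93% of co-culture replicates 1, 2 and 3. Their ratios to monoculture replicate 3 had medians of 1.92 (range 1.74 to 10.2), 1.27 (1.13 to 4.19) and 10.4 (5.96 to 13.9, chosen at 5 or more) in co-culture replicates 1, 2 and 3. For co-culture replicates 1 and 2 the SDs of the log2 ratio were 0.601 and 0.443, which is 0.501 and 0.349 of the SD over 563 other unigenes at least 4 times higher in the co-culture and of at least 10 TPM there, 0.458 and 0.353 over 1166 without that minimum, and 0.471 and 0.343 over 198 nearer in level; the line for a common source, under 0.5 in each, was not met in the first, the sets stand at lower levels in monoculture replicate 3 than the 22, the last 2 sets were added after the first was seen, and a common source stays open. Material of co-culture replicate 3 mixed into monoculture replicate 3 would need a mixed-in fraction of 9.61% to give the level of the 22 there. The 23 unigenes high in co-culture replicate 3 alone (median 340 TPM) stood lower in monoculture replicate 3. Their median there was 0.947% of their level in co-culture replicate 3 (95% interval 0.335% to 5.46%, unigenes taken as independent), with 19 of 23 under 9.61%. The 563 other unigenes went the other way. Their median ratio of co-culture replicate 3 to monoculture replicate 3 was 9.59 (quartiles 6.47 and 14.2), near the 10.4 of the 22. Yet the 563 were nearly as high in monoculture replicate 1 (median ratio of replicate 3 to replicate 1 of 1.26). Such mixing as the whole cause stays open.

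The second pattern is the low level in the monoculture of the 1215 unigenes that are at least 4 times higher in the co-culture, at medians of 0.709, 0.631 and 0.914 TPM in replicates 1, 2 and 3. Reads carried over from the co-culture libraries in fixed fractions were estimated from the fifth-lowest unigene per pair of libraries with a 2-fold allowance. These unigenes stand at 93.7 to 1619 TPM in the co-culture. The estimate was 40.9%, 37.2% and 38.1% of the level of the 1215 in replicates 1, 2 and 3. Another used the median fractions of unigenes high in only 1 co-culture library (8, 2 and 23 for replicates 1, 2 and 3). It gave 56.5%, 45.6% and 30.5%, so the first values are not upper limits. The best mix of co-culture libraries that gives the whole level was also tried. Of members it predicted at 10 TPM or more, 7.89%, 8.75% and 4% were seen under 1/5 of that. Between monoculture replicates this was up to 6.34%. The first estimate uses unigenes picked for a low ratio, and the second rests on few unigenes. In the last test the members missed were 6 of 76, 7 of 80 and 5 of 125 in replicates 1, 2 and 3. That is above 6.34% in replicates 1 and 2 only, by few unigenes. None of these values decides, and carry-over as the whole cause stays open. Reads of Streptococcus thermophilus assigned to similar sequences stay open: over pairs of unigenes that the 4-fold limit leaves free, the monoculture level followed the co-culture level (conditional Kendall tau of at least 0.173, bootstrap SE 0.037), which decides nothing, since similar genes may be high in both bacteria. A candidate explanation that also stays open is that small amounts of RNA from the second bacterium, or from a related one in the milk, were in the monoculture samples before the libraries were made. No taxon was assigned here, so that the 1215 unigenes come from Levilactobacillus brevis is itself a hypothesis.

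The third pattern is that monoculture replicate 1 has no value of 0. Had unigenes at 0 there been left out after scaling, the other columns would fall short of 1000000; unigenes at 0 in another library carry 2.89 to 33.4 TPM in the remaining libraries, and the largest deviation of a column sum was 0.0012 TPM. A selection of unigenes before scaling stays open, and no biological explanation was tested.

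The real split gave 1471 changed unigenes over all and 1470 among those detected in S, and the highest of the other 9 splits of the 6 libraries gave 0 in both. Only 1 of 10 splits was as large, the real one, and 10 splits are too few for a share under 0.05. Each of the other 9 splits also mixed both groups in both arms. The group difference then counts as spread, so few or no calls were likely there, and 0 is no measure of chance.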
